A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

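Total RNA from haploid yeast cultures, grown at 30 °C to an optical density at 600 nm of 0.6 to 0.7 per the labels, was labelled and hybridised to Affymetrix Yeast 2.0 arrays, which carry probe sets for Saccharomyces cerevisiae and Schizosaccharomyces pombe. The 14 arrays were assigned to 6 groups in 3 experiments from the sample labels, which call the replicates biological. The growth medium is not given in the sources used here. The deposited values are intensity per probe set on a linear scale, made by the authors with the MAS5 algorithm per the labels. The software version and the scaling target are not given in the sources used here. From the values, the mean after trimming 2% of probe sets at each end was 500.2 to 500.3 on every array, so each array had been scaled to a common mean. The number of arrays limits the precision.

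Of 10928 probe sets, 5498 matched a single S. cerevisiae gene (5449 genes), 1746 belonged to S. pombe, 1 matched several genes and 3683 had no gene name in the annotation used. Gene names and the order of genes came from a RefSeq gene table of assembly R64. Where a gene had several probe sets (47 genes) the brightest was used. The S. pombe probe sets served as background. A gene was tested if its mean log2 value over all arrays exceeded the 95th percentile of the S. pombe means, which left 5415 genes and removed 34. An array was counted as above background for a gene where its signal exceeded the 95th percentile of S. pombe signals on that array, 7.28 to 16.7. Folds given as "at least" were computed against that level where a whole group lay below it. Among the tested genes, 112 are read by probe sets that match related sequences, and their paralogs cannot be separated.

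Values were put on the log2 scale with values under 1 set to 1. Linear models with 6 group means were fitted to all 14 arrays in limma 3.58.1 (R 4.3.3) with moderated variances and an intensity trend (prior degrees of freedom 4.12, residual 8). Each altered strain was compared with the wild type of its own experiment, the 3 differences between these changes were tested as interaction contrasts, and the 3 wild types were compared with each other. P-values were adjusted by the Benjamini-Hochberg method within each contrast and genes with an adjusted p under 0.05 were called. All limma and camera p-values are two-sided. For each of 41 gene lists, camera tested the list against all other genes with a preset correlation of 0.01 between genes, adjusted over 123 tests, and again with a correlation estimated per list (median 0.188), with which 0 lists were called in any of the 3 comparisons. The counts given as adjusted over the list alone used the members' p-values only. The fry test was run in its directional and mixed forms as an alternative.

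The comparisons, the 41 lists and the alternatives were chosen before the data were examined, except where the text says otherwise. Genes were named by a rule. It takes the targeted genes, the markers of the genotypes and the neighbours of the deleted genes. It adds the 12 highest and 12 lowest changes among called genes whose groups do not overlap and which are above background in every array of a group, and up to 4 members with the smallest adjusted p of each list with a call or a called member. Between comparisons it takes up to 10 genes called in both and up to 10 with the smallest p for the difference. Standard errors are those of the linear model, and signals are given with their standard deviation over replicates.

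The replicate numbers were checked for pairing by correlating, across genes, the deviations of same-numbered arrays from their group means, genes not being independent replicates. These correlations were 0.64, 0.62 and 0.69 for the 3 numbers of the JHD2 deletion experiment, 0.73 in the SET1 experiment and -0.14 in the overexpression experiment. The main fits have no term for pairs. A fit with the number as a block is an alternative, and some values of the JHD2 deletion experiment are given per pair. The 3'/5' ratio of an array is the mean log2 ratio of 3' to 5' control probe sets.

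The fit was tested on simulated data with 200 changed genes in each of 5 draws. At a log2 change of 1 it found 70.8% of the changed genes for the design of the set1 deletion, 80.4% for the jhd2 deletion and 76.8% for the overexpression, and at 0.5 it found 15.6%, 30.4% and 19.6%. Unchanged genes made up 3.86% to 5.40% of the calls. The simulated noise was independent between genes and arrays, with no pairs and no differences in array quality. These rates may therefore not hold for the real arrays. Alternatives were quantile normalization, median centring, other filters, a pseudocount of 32, no intensity trend, array weights, the arrays of an experiment alone, all wild types as 1 group, a replicate block, the mean of probe sets, other thresholds and leaving out each array in turn. A covariate for the 3'/5' ratio, leaving out both replicate 3 arrays of the JHD2 deletion experiment, and a crossed block were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Chromatin marks and protein levels were not analysed here.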

Results

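Expression was measured in haploid budding yeast (Saccharomyces cerevisiae) on 14 Affymetrix Yeast 2.0 arrays, each hybridised with RNA from 1 culture. The arrays form 3 experiments, each with its own wild type. The SET1 experiment had 2 wild-type and 2 set1 deletion arrays, and the JHD2 deletion experiment had 3 wild-type and 3 jhd2 deletion arrays. The overexpression experiment had 2 wild-type arrays and 2 arrays of a strain that overexpresses JHD2 while carrying the jhd2 deletion cassette. Set1 is the methyltransferase that adds methyl groups to lysine 4 of histone H3 (H3K4), and Jhd2 is the JmjC-domain demethylase that removes them. The comparisons address which effects of Jhd2 go through H3K4 methylation and which do not. The median signal of the 5415 tested genes lay between 538.1 and 664.3 per array, and 98.0% to 99.9% of them were above the background set by fission yeast probe sets. Arrays of the same group correlated at r = 0.958 to 0.989 across genes, which are not independent replicates, and arrays of different groups at 0.889 to 0.990. The 2 wild-type arrays of the SET1 experiment correlated at 0.958 with each other. With the set1 deletion arrays of the same number they correlated at 0.977 and 0.970. The number of arrays, 2 or 3 per group, limits the precision of every value.

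SET1 (YHR119W) gave signals of 1.13 and 3.31 on the set1 deletion arrays, against 395.4 to 701.2 on the other 12. JHD2 (YJR119C) gave 3.22, 3.41 and 0.23 on the jhd2 deletion arrays and 118.8 to 226.3 on the wild-type and set1 deletion arrays. On the overexpression arrays JHD2 reached 5207 and 6237. SET1 did not pass the test with either JHD2 change (log2 change 0.06 ± 0.31 SE with the deletion and 0.08 ± 0.37 with the overexpression). JHD2 did not pass it in the set1 deletion (0.28 ± 0.45, adjusted p = 0.972). Of the genes beside SET1 and JHD2 on their chromosomes, ORC6, MSH1, ILM1 and ATP2, none passed over all genes. ILM1, beside JHD2, was lower over its own list of 4 neighbours in both strains with a changed JHD2 gene, with log2 changes of -0.53 ± 0.18 and -0.71 ± 0.22.

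**Figure D1:**
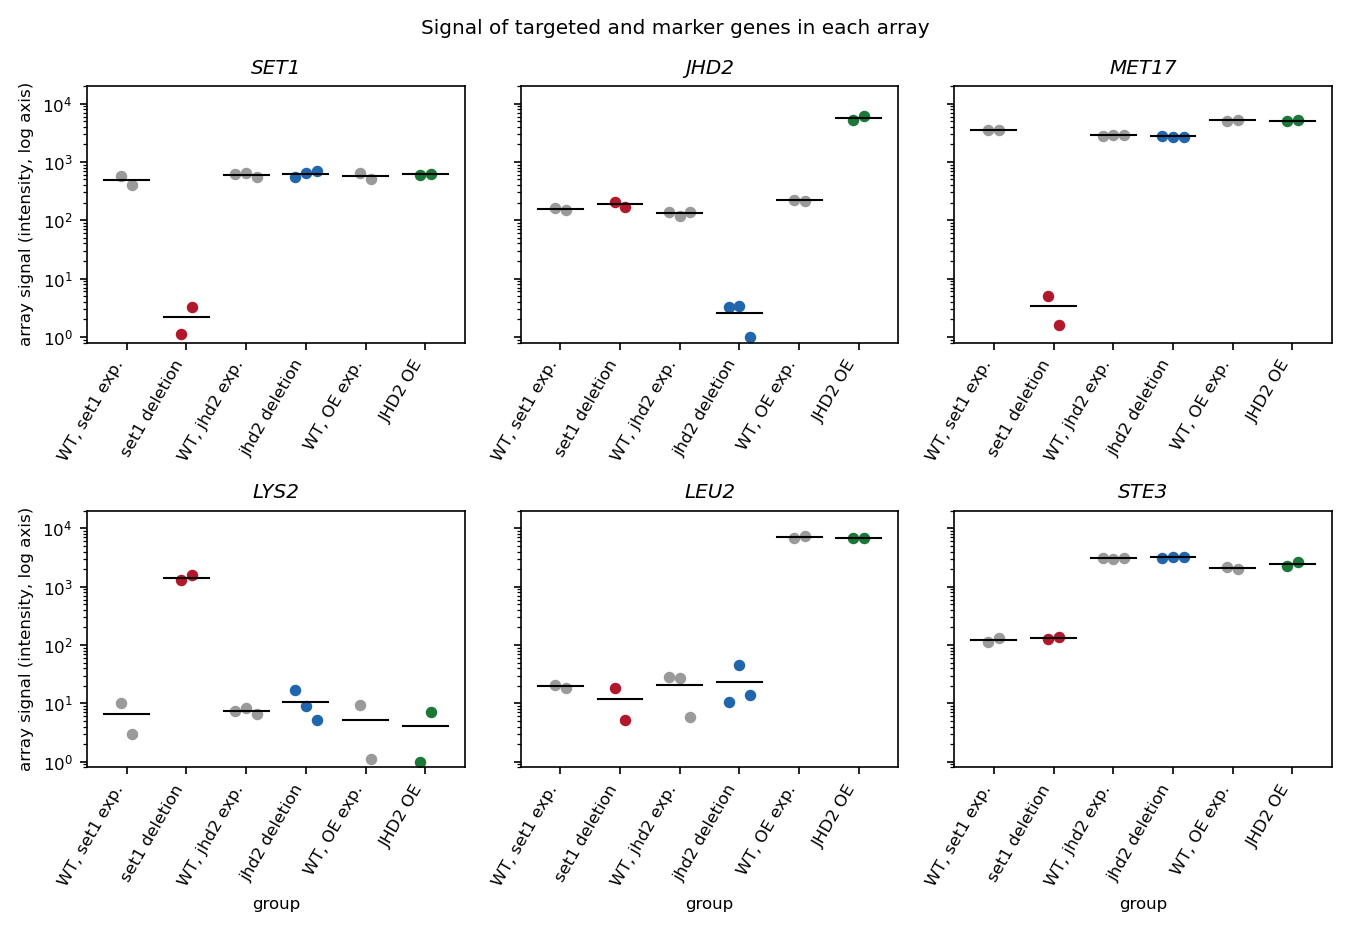
Array signal (MAS5 intensity, log axis, values under 1 drawn at 1) of SET1, JHD2, MET17, LYS2, LEU2 and STE3 on each of the 14 arrays, with 1 point per array and a bar at each group's mean. JHD2 is at 5207 and 6237 on the overexpression arrays and at 3.41 or less on the 3 jhd2 deletion arrays.

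Marker genes also differed between strains. MET17 (YLR303W), the O-acetylhomoserine sulfhydrylase gene also called MET15, was at background in the set1 deletion, whose genotype lists met15, and at group means of 2747 to 5139.9 elsewhere. LYS2, which encodes aminoadipate reductase, gave a mean of 1437 in the set1 deletion, whose genotype does not list lys2, and 10.5 or less in the other groups. LEU2 gave means of 7085 ± 296 and 6859 ± 50.7 (SD, n = 2 each) in the wild type and the altered strain of the overexpression experiment, and 23.5 or less in the other groups. The a-specific mating genes, transcribed in MATa cells, had median signals of 1141 and 1047 in the wild type and deletion of the SET1 experiment and of 32.6 to 52.4 in the other 4 groups. The alpha-specific genes, transcribed in MATalpha cells, showed the opposite levels, with 123.7 and 130.5 in the SET1 experiment and 2768 to 3769 elsewhere. The labels give every wild type the same genotype. The mating-type and LEU2 signals thus show differences between the wild types that the labels do not give.

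The set1 deletion strain differed from its wild type in 14 of 5415 genes at an adjusted p under 0.05, with 9 higher and 5 lower (6 and 6 after quantile normalization), and 451 genes had an unadjusted p under 0.05. Deviations of same-numbered arrays correlated at 0.73 across genes in this experiment. With the replicate numbers as a block 110 genes were called, 55 higher and 55 lower. MET17 was at least 350.1-fold lower in the deletion (signal 3.32 ± 2.46 against 3521 ± 10.0, SD, n = 2 each, adjusted p = 7.8e-09). SET1 itself was at least 47.4-fold lower (adjusted p = 1.6e-07). LYS2 was at least 136.8-fold higher (1437 ± 184 against 6.48 ± 5.01, adjusted p = 0.00566). MET17 and LYS2 are markers that differ between the genotypes of the deletion and its wild type, so 3 of the 14 genes are the target or a marker. The strains thus differ at more loci than SET1, and for the other 11 genes and for the gene lists the comparison does not separate the loss of SET1 from other differences between the strains. Groups did not overlap for 36.5% of genes, where chance gives 33.3% for arrays that do not vary in pairs.

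Alpha-specific genes moved in both directions in these MATa-type arrays. MF(ALPHA)1 and MF(ALPHA)2, which encode the alpha-factor pheromone, rose by 1.06 ± 0.13 and 1.09 ± 0.17 on the log2 scale (SE, n = 2 against 2, adjusted p = 0.00397 and 0.0199), from signals of 12.6 and 17.3. Those wild-type signals were near the background, which was 11.5 and 9.47 on the 2 wild-type arrays. AFB1 (YLR040C), an alpha-specific gene for a barrier to a-factor, fell by 1.2 ± 0.12 from 348.0 to 151.7 (adjusted p = 0.000618). Of the 5 alpha-specific genes, 2 were higher and 1 lower over all genes and adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.188).

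The 6 other genes that were higher have varied functions. SPO74, a component of the meiotic spindle pole body, rose by 2.35 ± 0.40 (51.8 ± 5.85 against 10.2 ± 0.875, adjusted p = 0.0304), and LOH1, a gene needed for spore wall formation, rose by 1.99 ± 0.34. SRL4, a gene linked to suppression of the loss of the Rad53 checkpoint kinase, was at least 4.23-fold higher (adjusted p = 0.0304). HUG1, which inhibits ribonucleotide reductase and is induced by DNA damage, rose 2.66-fold from 255.6 ± 69.7 to 666.1 ± 1.71 (adjusted p = 0.0190). DMA2, a ubiquitin ligase of the spindle position checkpoint, rose 1.80-fold (adjusted p = 0.0201), and YNR064C, an epoxide hydrolase gene, rose 4.72-fold (adjusted p = 0.00566). The 2 remaining genes were lower: YJR015W, of unknown function, at -0.69 ± 0.10 (adjusted p = 0.0133) and FDC1, a ferulic acid decarboxylase gene, at -0.82 ± 0.15 (adjusted p = 0.0463).

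Nutrient and growth lists moved by smaller amounts, with 9 of 41 lists called by camera, which tests a list against all other genes. Lysine biosynthesis genes, in a pathway whose genotype differs between the strains (LYS2), were higher in 9 of 10 cases (median 0.24, adjusted p = 0.000119), with 1 gene higher over all genes and 3 adjusted over the list alone: LYS2, the homocitrate synthase gene LYS20 (0.72 ± 0.14) and the saccharopine dehydrogenase gene LYS9 (0.60 ± 0.13). Adjusted p = 0.397 with an estimated correlation for this list. The phosphate (PHO) regulon was lower in 16 of 19 genes (median -0.27, adjusted p = 6.7e-05), with 0 members passing and values of -1.09 ± 0.35 for the sodium-phosphate transporter gene PHO89 and -1.26 ± 0.49 for SPL2, which restrains low-affinity phosphate uptake. The iron regulon was lower in 19 of 29 genes (median -0.18, adjusted p = 0.00362), with 1 member lower adjusted over the list alone, the cell wall mannoprotein gene FIT3 (-0.95 ± 0.23). Adjusted p = 0.756 with an estimated correlation for each of these 2 lists. Thiamine genes were higher in 10 of 15 cases (median 0.16, adjusted p = 0.0296, and adjusted p = 0.539 with an estimated correlation). The thiazole synthase gene THI4 (0.96 ± 0.18) and THI13 (0.76 ± 0.22), for the pyrimidine moiety of thiamine, were higher adjusted over that list alone.

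Ribosome biogenesis genes were higher in 102 of 106 cases (median 0.20, adjusted p = 4.1e-08) with 0 members passing, PWP2, for a small-subunit processome protein, being at 0.61 ± 0.23. G1/S and S-phase genes were higher in 22 of 24 (median 0.22, adjusted p = 0.00204), with the S-phase cyclin CLB6 at 1.44 ± 0.43 and not passing. Anaerobic mannoprotein and seripauperin genes were higher in 17 of 19 (median 0.32, adjusted p = 0.00221), and 1 of them, the cold-shock mannoprotein gene TIR1 (0.78 ± 0.19), passed adjusted over the list alone. Chaperones controlled by heat shock factor were higher in 23 of 25 (median 0.17, adjusted p = 0.00464), with CUR1, a sorting factor for misfolded proteins, at 1.15 ± 0.37 and not passing. Adjusted p = 0.756 with an estimated correlation for each of these 4 lists. Meiosis and sporulation genes were higher in 26 of 36 (median 0.47, adjusted p = 0.000891, and adjusted p = 0.590 with an estimated correlation), with 0 members passing and the septins SPR3 and SPR28 at 1.21 ± 0.32 and 1.31 ± 0.37. Quantile normalization left this list uncalled (adjusted p = 0.269).

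Part of these calls changed when single arrays were left out. Same-numbered arrays of this experiment vary together (r = 0.73 across genes), so leaving out 1 also breaks a pair. The changes below are not separated from that. With the replicate block, which models the pairs, 8 of the 9 lists were called. The count of 14 genes became 3 and 4 without set1 deletion replicates 1 and 2, 6 without wild-type replicate 2, and 24 without jhd2 deletion replicate 3. A limma fit to the 4 arrays of this experiment alone called 0 genes, with 370 at an unadjusted p under 0.05. SET1, MET17 and AFB1 kept their calls without any 1 of the 14 arrays, and the other 11 genes lost theirs without 1 to 11 arrays, set1 deletion replicate 1 among them each time. Of the lists, phosphate and lysine kept their calls throughout. Without wild-type replicate 1 the chaperone list was at -0.02 (adjusted p = 0.842), iron at -0.09 (0.481), meiosis at 0.39 (0.0573) and the mannoproteins at 0.34 (0.0759). Without wild-type replicate 2 ribosome biogenesis was at -0.01 (adjusted p = 0.771), G1/S at 0.15 (0.197) and thiamine at 0.16 (0.173). The chaperone, mannoprotein and thiamine calls were also lost without set1 deletion replicate 2, and thiamine without wild-type replicate 1. Among the 7 other COMPASS subunits, partners of Set1, 0 passed: the list's median was 0.03 and its mean -1.0, which rests on SET1 itself.

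**Figure D2:**
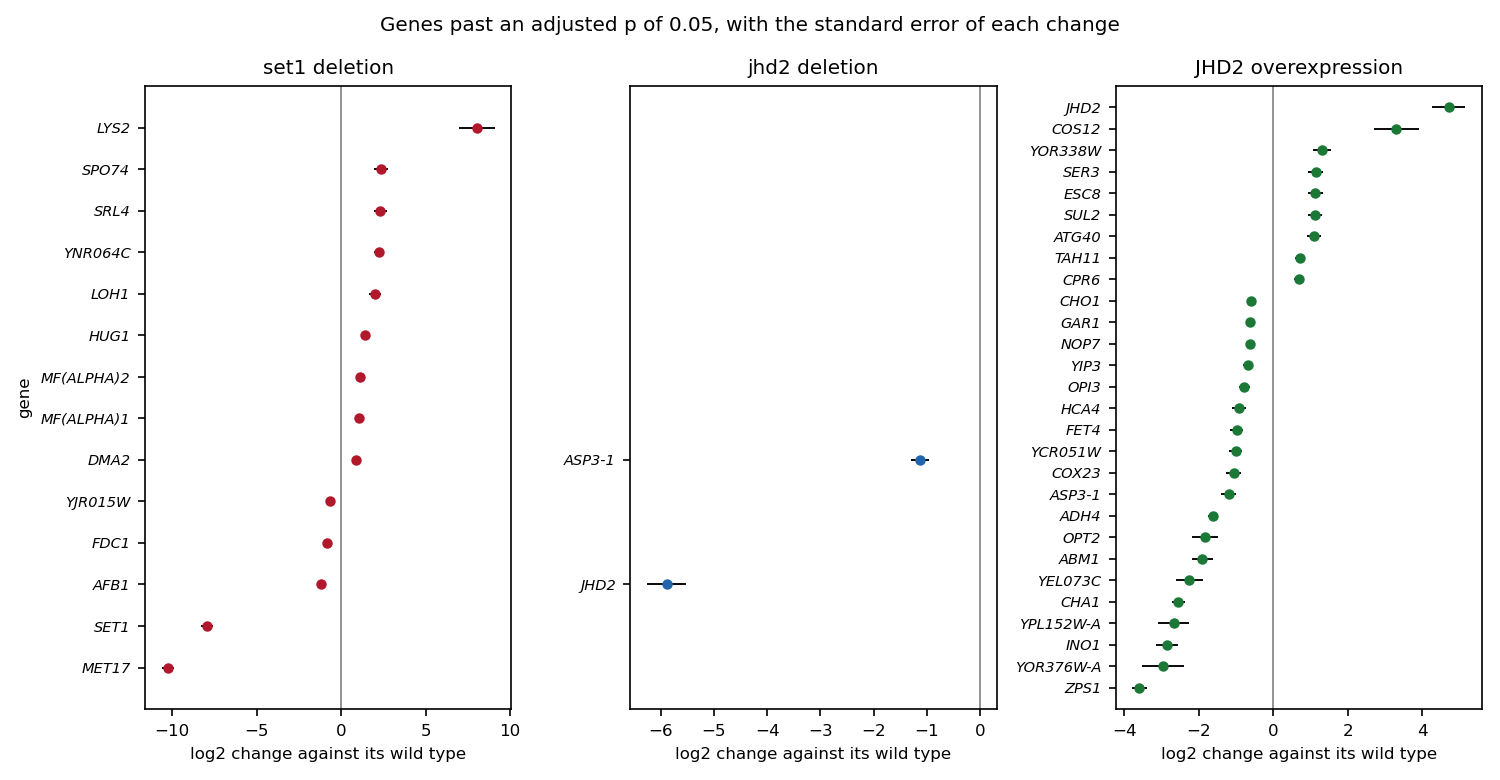
Log2 change (x axis, altered strain against the wild type of its experiment) of each gene with an adjusted p under 0.05 in the 3 comparisons, with bars of 1 standard error. The set1 deletion shows 14 genes, the jhd2 deletion 2 and the JHD2 overexpression 28.

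The jhd2 deletion strain differed from its wild type in 2 genes, both lower, and 99 genes had an unadjusted p under 0.05. JHD2 was at least 11.1-fold lower (signal 2.29 ± 1.78 against 132.3 ± 11.7, SD, n = 3 each, adjusted p = 8.6e-06). ASP3-1 (YLR155C), 1 of the copies of the cell wall L-asparaginase gene that is induced by nitrogen starvation, fell by 1.12 ± 0.17 from 4010 ± 658 to 1823 ± 90.7 (adjusted p = 0.0485). Its probe set is shared among the copies, so the copies cannot be separated. With the replicate numbers as a block, 4 genes were called: these 2 and YLR156W and YLR157W-E, open reading frames in the same repeat, with changes of -1.79 ± 0.48 and -1.94 ± 0.41 in the fit with no block, chosen after their values were seen. Groups did not overlap for 4.78% of genes. Chance gives 10% for unpaired arrays, and the pairing of the replicate numbers makes overlap more likely, so 10% is not the value for no change here. ASP3-1 lost its call, and the count was 1, without wild-type replicate 1 or 2, jhd2 deletion replicate 1 or 2, or any 1 of the 4 arrays of the overexpression experiment. The count was 24, with 19 higher and 5 lower, without jhd2 deletion replicate 3, and 169, with 162 higher and 7 lower, without both replicate 3 arrays, an alternative chosen after seeing the data. The deletion arrays left in these settings, replicates 1 and 2, stand apart in their signal distribution. They had the highest median signals of fission yeast probe sets of all arrays (3.72 and 3.07) and the lowest medians of tested genes (565.0 and 538.1). Array weights gave 231 genes, 199 higher and 32 lower.

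Highly expressed housekeeping groups were slightly higher in the jhd2 deletion on the deposited scale. Cytosolic ribosomal protein genes were higher in 126 of 128 cases (median 0.25, adjusted p = 1.7e-75), for example RPL28 (0.34 ± 0.12) and RPL6B (0.33 ± 0.11), with 0 passing alone, and after quantile normalization their median was 0.02 (adjusted p = 0.000716). Glycolysis and fermentation genes were higher in 19 of 23 (median 0.23, adjusted p = 8.05e-14), for example the aldolase gene FBA1 (0.29 ± 0.12) and the phosphofructokinase gene PFK1 (0.21 ± 0.08), and quantile normalization left them at 0.02 and uncalled (adjusted p = 0.111). Adjusted p = 0.397 with an estimated correlation for both lists. The medians of ribosomal protein genes were 0.36 and 0.55 in pairs 1 and 2 and -0.19 in pair 3, whose arrays had the higher 3'/5' ratios (1.50 and 1.33 on the log2 scale, against means of 0.57 and 0.55 in pairs 1 and 2). Mitochondrial ribosomal protein genes were lower in 63 of 70 (median -0.11, adjusted p = 0.000217, and adjusted p = 0.756 with an estimated correlation), with the large-subunit gene MRPL8 at -0.38 ± 0.10 and not passing, and quantile normalization left them uncalled (adjusted p = 0.0957).

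**Figure D3:**
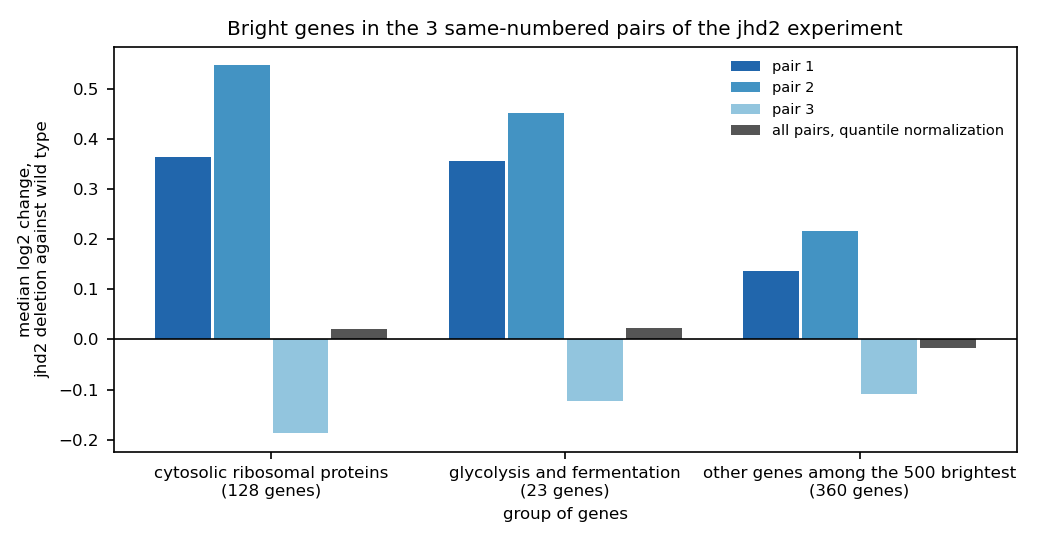
Median log2 change (y axis, jhd2 deletion against wild type) of 128 cytosolic ribosomal protein genes, 23 glycolysis genes and 360 other bright genes in the 3 same-numbered pairs of arrays, and over all pairs after quantile normalization. Pairs 1 and 2 are above 0 and pair 3 below it in each group of genes.

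Histone genes were higher in 7 of 10 cases (median 0.19, adjusted p = 0.00266, and adjusted p = 0.756 with an estimated correlation), with HTB2, for histone H2B, at 0.28 ± 0.13, and quantile normalization turned the median to -0.03 and left the list uncalled (adjusted p = 0.295). The 7 a-specific mating genes, low in these MATalpha-type arrays, had a median of 0.32 (adjusted p = 0.00266, and adjusted p = 0.539 with an estimated correlation), MFA2, for the a-factor pheromone, being at 0.59 ± 0.21 with signals of 37.9 against 25.6. The fission yeast probe sets that serve as background had a median of 0.32 in the same comparison, and quantile normalization left the a-specific list at 0.01 and uncalled (adjusted p = 0.513). Alpha-specific genes had a median of 0.10 (adjusted p = 0.0286, adjusted p = 0.744 with an estimated correlation, and 0.784 after quantile normalization, with a median of 0.02). Flocculins were higher in 6 of 7 (median 0.27, adjusted p = 0.0025), with FLO10 at 0.37 ± 0.18, and G2/M and M/G1 genes in 19 of 21 (median 0.06, adjusted p = 0.0481), with the chitinase gene CTS1 at 0.19 ± 0.14. Cell wall integrity targets had a median of 0.06 (adjusted p = 0.0115), with the glucan synthase gene FKS1 at 0.24 ± 0.13, and were uncalled after quantile normalization (median 0.01, adjusted p = 0.678) and median centring (adjusted p = 0.0552). Adjusted p = 0.756 with an estimated correlation for each of these 3 lists. Without wild-type replicate 3 the flocculin median turned to -0.03 and the median of cell wall targets to -0.04. Thiamine genes were higher in 12 of 15 (median 0.09, adjusted p = 0.00823, and adjusted p = 0.397 with an estimated correlation).

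Ergosterol biosynthesis genes had a median of 0.03 (adjusted p = 0.0410, and 0.0542 with the block) and meiosis genes of 0.09 (adjusted p = 0.0410, and 0.0558 with the block), and quantile normalization left both uncalled, at 0.002 for ergosterol (adjusted p = 0.668) and -0.11 for meiosis (adjusted p = 0.15). Median centring left meiosis uncalled as well (adjusted p = 0.19). Adjusted p = 0.756 with an estimated correlation for both. The JmjC-domain list, 5 genes, had a median of -0.05 (0.01 after quantile normalization and 0.02 after median centring) and a mean of -1.2, which rests on JHD2 (adjusted p = 0.00494, 0.0629 with the block, and adjusted p = 0.397 with an estimated correlation), and its other 4 members, among them the demethylase genes RPH1 and GIS1, did not pass. The block added 2 lists: COMPASS subunits, lower in 7 of 8 genes (median -0.17, adjusted p = 0.0613 with no block, 0.0453 with it, and 0.15 after quantile normalization, with a median of -0.11), and genes near telomeres (median 0.01, turned to -0.02 by quantile normalization, adjusted p = 0.0875 and 0.0444), with adjusted p = 0.756 at an estimated correlation for both. Of the 13 lists called with no block, the ribosomal protein, mitochondrial ribosomal protein, glycolysis and JmjC lists kept their calls without any 1 array. Each of the other 9 lost its call without 2 to 4 of the 6 arrays of this experiment, every one of which ended some of the calls, and the highest adjusted p of each lay between 0.109 for thiamine, without wild-type replicate 3, and 0.652 for ergosterol, without wild-type replicate 1.

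The JHD2 overexpression strain differed from its wild type in 28 genes, 9 higher and 19 lower, and 1049 genes had an unadjusted p under 0.05. Quantile normalization gave 121 genes, 49 higher and 72 lower, and median centring 13, 4 higher and 9 lower. JHD2 was 26.1-fold above its wild type (5722 ± 728 against 218.4 ± 11.1, SD, n = 2 each, adjusted p = 0.000274). ZPS1 (YOL154W), a zinc-regulated cell surface protein gene, fell by 3.59 ± 0.19 on the log2 scale, from 5834 ± 111 to 483.8 ± 34.6 (adjusted p = 1.3e-06). The catabolic serine and threonine deaminase gene CHA1 fell by 2.55 ± 0.17 (adjusted p = 8.8e-06) and ADH4, for a zinc-responsive alcohol dehydrogenase, by 1.62 ± 0.13 (adjusted p = 5.6e-05). INO1, for inositol-3-phosphate synthase, the first step of inositol synthesis, fell by 2.85 ± 0.30 from 468.9 ± 28.4 to 66.8 ± 22.6 (adjusted p = 0.000521). JHD2, ZPS1, CHA1, ADH4 and INO1 kept their calls without any 1 of the 14 arrays.

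Among the other lower genes were OPT2, an oligopeptide transporter gene (-1.84 ± 0.35), FET4, a low-affinity iron and zinc transporter gene (-0.98 ± 0.18), and COX23, for a protein of copper delivery to cytochrome oxidase (-1.06 ± 0.21), with adjusted p between 0.0463 and 0.0498. The phospholipid synthesis genes OPI3 and CHO1 were at -0.78 ± 0.15 and -0.59 ± 0.12 (adjusted p = 0.0479 and 0.0498) and were chosen after their values were seen. ASP3-1 fell by 1.19 ± 0.20 (adjusted p = 0.0340), as its shared probe set did in the jhd2 deletion, and ABM1, a gene of microtubule organisation, fell by 1.91 ± 0.28 (adjusted p = 0.0138). GAR1, for a snoRNA-binding protein, and NOP7, for a 60S assembly factor, were at -0.62 ± 0.10 and -0.62 ± 0.11 (adjusted p = 0.0340 each). Small or uncharacterised open reading frames were lower as well: YEL073C (-2.25 ± 0.37), YPL152W-A (-2.68 ± 0.42), YOR376W-A (-2.97 ± 0.57) and YCR051W (-1.01 ± 0.18).

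The 8 other genes that were higher in this strain included COS12, a subtelomeric membrane protein gene, by 3.30 ± 0.60 (106.5 ± 29.8 against 10.6 ± 1.09, adjusted p = 0.0401). The sulfate permease gene SUL2 and the phosphoglycerate dehydrogenase gene SER3, at the entry to serine synthesis, rose by 1.13 ± 0.19 and 1.14 ± 0.20 (adjusted p = 0.0316 and 0.0340). ATG40, an autophagy receptor of the endoplasmic reticulum, rose by 1.10 ± 0.19, and ESC8, a gene linked to silencing, by 1.13 ± 0.21. YOR338W, of unknown function, rose by 1.30 ± 0.24, TAH11, for a replication licensing factor, by 0.71 ± 0.13 and CPR6, an Hsp90 co-chaperone gene, by 0.69 ± 0.13, with adjusted p from 0.0461 to 0.0479.

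**Figure D4:**
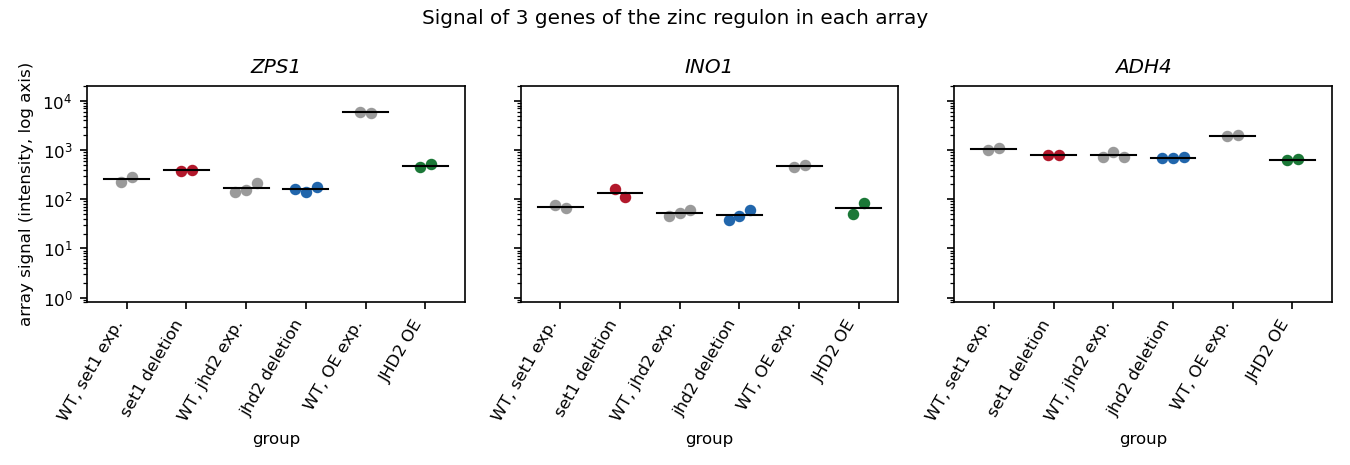
Array signal (MAS5 intensity, log axis) of ZPS1, INO1 and ADH4, members of the zinc regulon list, on each of the 14 arrays, with 1 point per array and a bar at each group's mean. The wild type of the overexpression experiment has the highest mean of all 6 groups for ZPS1, 5834.

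The zinc regulon was lower in 10 of 11 genes (median -0.61, adjusted p = 1.8e-07, and adjusted p = 0.397 with an estimated correlation). ZPS1, ADH4 and INO1 passed over all genes and 7 members adjusted over the list alone, with its activator gene ZAP1 at -1.03 ± 0.23. Ribosome biogenesis genes were lower in 85 of 106 (median -0.21, adjusted p = 9.5e-07), with 2 lower over all genes, 14 adjusted over the list alone, and BUD23, for an 18S rRNA methyltransferase, at -1.30 ± 0.27. Heat shock factor chaperones were higher in 19 of 25 (median 0.21, adjusted p = 0.00266), with CPR6 passing over all genes and 3 members, CPR6, STI1 (0.54 ± 0.11) and AHA1 (0.57 ± 0.16), adjusted over the list alone. Adjusted p = 0.756 with an estimated correlation for both of these lists.

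Branched-chain amino acid genes were higher in 11 of 12 (median 0.14, adjusted p = 0.0303), 2 of them adjusted over the list alone, the oxaloacetate carrier gene OAC1 (0.65 ± 0.18) and the aminotransferase gene BAT2 (0.51 ± 0.15), and median centring left the list uncalled (adjusted p = 0.0550). Cell wall integrity targets were lower in 20 of 26 (median -0.24, adjusted p = 0.0415), 1 of them adjusted over the list alone, the transglycosylase gene CRH1 (-1.03 ± 0.22). Hexose transporters were lower in 12 of 15 (median -0.36, adjusted p = 0.0469), 1 of them adjusted over the list alone, HXT2 (-0.83 ± 0.19), and quantile normalization left this list uncalled (adjusted p = 0.269). Adjusted p = 0.756 with an estimated correlation for each of these 3 lists. Among 227 genes near telomeres, 1 was higher and 5 were lower over all genes, and the list did not pass (median -0.18, turned to 0.03 by quantile normalization, adjusted p = 0.0710). In the sulfur and methionine list 1 of 33 genes passed, SUL2, and the list did not (adjusted p = 0.0993).

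The overexpression arrays had a mean log2 3'/5' ratio of 1.43 against 0.77 in their wild type, while the set1 deletion had 0.76 against 0.75 and the jhd2 deletion 0.81 against 0.88. With the ratio as a covariate, added after the ratios were seen, 29 genes were called in the overexpression, 12 of them among the 28. The covariate left 4 of the 6 lists called, with 9 lists called in all. It ended the calls of hexose transporters (median -0.60 against -0.36 without it, adjusted p = 0.0559) and cell wall targets (median -0.08 against -0.24, adjusted p = 0.237). With no covariate, groups did not overlap for 63.0% of genes, where chance gives 33.3%. The count of 28 became 5 or 7 without either overexpression array or either of its wild-type arrays, and 9 without either set1 deletion array. A fit to the 4 arrays of this experiment alone called 955 genes, 402 higher and 553 lower, all 28 among them. They were set beside the difference of wild-type replicate 3 from replicates 1 and 2 in the JHD2 deletion experiment, after seeing the data. Of 954 called genes other than JHD2, 808 (84.7%) had the sign of that difference, against 68.5% of all tested genes. Of the 28 calls, 17 of the 27 other than JHD2 had it (63.0%). In the fit to all 14 arrays the count of 28 became 13, 10 and 15 without wild-type replicate 1 or 2 or deletion replicate 1 of the JHD2 deletion experiment, and 157 and 79 without wild-type or deletion replicate 3. Apart from the 5 genes named above, each of the 19 other genes named by the rule lost its call without 3 to 12 arrays, 2 or more arrays of the overexpression experiment among them, with a highest adjusted p of 0.358. The zinc, ribosome biogenesis and chaperone lists kept their calls without any 1 array. Against all 7 wild-type arrays as 1 group the zinc list was at 0.02 (adjusted p = 0.653), ZPS1 at -0.10 (0.964), INO1 at -0.72 (0.579), ADH4 at -0.79 (0.149) and the chaperone list at 0.02 (0.898), none of them called. Branched-chain genes lost theirs without overexpression replicate 1 or wild-type replicate 1 of that experiment (adjusted p up to 0.223). Cell wall targets lost theirs without overexpression replicate 1 or wild-type replicate 2 of that experiment, and hexose transporters without overexpression replicate 2 or wild-type replicate 1 of it (adjusted p up to 0.147 and 0.35). Both were also lost without either wild-type array of the SET1 experiment or wild-type replicate 2 of the JHD2 deletion experiment, and hexose transporters without either replicate 3 array.

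Shared and separate effects of SET1 and JHD2 were tested by comparing the changes themselves. The SET1 experiment has MATa-type and the others MATalpha-type expression of mating genes, and the set1 deletion differs from its wild type at more loci than SET1, so differences between these changes are not separated from differences in mating type or strain. Between the set1 and jhd2 deletions, 0 genes were called in both. With so few calls 0.0018 were expected in the same direction and 0.0033 in opposite directions, so this count does not decide whether effects are shared. In both comparisons 10 genes had an unadjusted p under 0.05 with the same direction, where 4.25 were expected, and 2 with opposite directions, where 4.0 were expected. The changes correlated at r = 0.14 across genes (jackknife SE 0.12), which are not independent replicates, and those of fission yeast probe sets at 0.002. The test of the difference called 4 genes, 1 higher and 3 lower in the set1 deletion (3 and 3 after quantile normalization): MET17, SET1, JHD2 and AFB1, the last, an alpha-specific gene, with a difference of -1.31 ± 0.16 (adjusted p = 0.00291). HUG1 differed by 1.59 ± 0.28 and did not pass (adjusted p = 0.0776), and 247 genes had an unadjusted p under 0.05. The count was 8 without wild-type replicate 1 of the SET1 experiment.

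Between the set1 deletion and the JHD2 overexpression, 0 genes were called in both, where 0.033 were expected in the same direction and 0.040 in opposite directions. At an unadjusted p under 0.05, 56 genes moved in the same direction and 43 in opposite directions, where 43.2 and 44.2 were expected, and the changes correlated at r = 0.04 (jackknife SE 0.17). The test of the difference called 14 genes, 10 higher in the set1 deletion and 4 lower (16 and 11 after quantile normalization). ZPS1 differed by 4.21 ± 0.27 (adjusted p = 5.6e-06), INO1 by 3.77 ± 0.42 and CHA1 by 2.19 ± 0.24 (adjusted p = 0.00106 each). The damage-induced gene HUG1 differed by 2.40 ± 0.31 (adjusted p = 0.00400), being higher in the set1 deletion and at -0.99 in the overexpression, where it did not pass (adjusted p = 0.0579). ADH4 and OPT2 differed by 1.21 ± 0.19 and 3.02 ± 0.50 (adjusted p = 0.0185 and 0.0311), and AFB1 by -1.03 ± 0.17 (adjusted p = 0.0311). The count was 6 to 9 without either set1 deletion array, any array of the overexpression experiment, or replicate 1 or 2 of either group of the JHD2 deletion experiment.

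Between the loss and the gain of JHD2, 2 genes were called in both: JHD2 itself, altered in both strains by design, in opposite directions, and ASP3-1, in the same direction. ASP3-1 differed by 0.07 ± 0.26 between them (adjusted p = 0.918). The changes correlated at r = -0.10 (jackknife SE 0.62), and at an unadjusted p under 0.05 11 genes moved the same way and 8 oppositely, where 9.01 and 10.2 were expected. The test of the difference called 5 genes: JHD2, ZPS1 (3.51 ± 0.25, adjusted p = 1.6e-05), CHA1 (2.58 ± 0.22, adjusted p = 9.5e-05), ADH4 (1.47 ± 0.17, adjusted p = 0.0021) and INO1 (2.70 ± 0.38, adjusted p = 0.0131). Each of the last 4 was called lower with overexpression, against its own wild type, and not with deletion. ZPS1, INO1 and ADH4 were higher in that wild type than in that of the JHD2 deletion experiment. Against all wild-type arrays joined, their changes with overexpression were -0.10, -0.72 and -0.79, not called (limma adjusted p = 0.964, 0.579 and 0.149), while CHA1 kept its call. For ZPS1, INO1 and ADH4 the test thus does not separate the gain of JHD2 from a difference between the wild types. The test of the difference called 65 genes without jhd2 deletion replicate 3.

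The wild types of the 3 experiments were compared because each altered strain is read against its own. The wild types of the JHD2 deletion and SET1 experiments differed in 21 genes, 8 higher and 13 lower in the former (9 and 9 after quantile normalization), among them all 5 alpha-specific genes, higher, and all 7 a-specific genes, lower. The wild type of the overexpression experiment differed from that of the SET1 experiment in 439 genes, 284 higher and 155 lower, and from that of the JHD2 deletion experiment in 880, 582 higher and 298 lower. Median centring gave 148 higher and 355 lower, and 436 higher and 558 lower, in those comparisons, while quantile normalization gave 193 and 212, and 387 and 473, so the direction of the majority rests on the scaling. ZPS1 was higher by 5.13 ± 0.17 in the wild type of the overexpression experiment than in that of the JHD2 deletion experiment (adjusted p = 6.3e-09), INO1 by 3.16 ± 0.27, the phosphoglyceride methyltransferase gene OPI3 by 1.74 ± 0.14 and ADH4 by 1.35 ± 0.12 (adjusted p up to 1.95e-05). The acid phosphatase gene PHO11 and the copper transporter gene CTR1 were lower there, at -3.84 ± 0.23 and -3.44 ± 0.19 (adjusted p = 1.2e-06 and 8.8e-07). The genes named here were chosen after their values were seen. Without wild-type replicate 1 of the SET1 experiment the counts of 21 and 439 became 224 and 240, and the count of 880 became 581 without wild-type replicate 2 of the JHD2 deletion experiment. Without wild-type replicate 1 or 2 of the overexpression experiment the count of 439 became 124 or 199 and that of 880 became 257 or 382. The count of 439 was also between 283 and 290 without either set1 deletion or overexpression array or jhd2 deletion replicate 1.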

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

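All tests in this part were chosen after the results they examine were seen.

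Probe sets with no yeast gene name in the annotation used gave signals above the wild-type arrays in 4 cases. A reporter control probe set of the array had a mean signal of 8332 ± 75.3 in the set1 deletion (SD, n = 2), 8344 ± 1536 in the jhd2 deletion (n = 3) and 6267 ± 36.8 in the JHD2 overexpression (n = 2). Its means in the wild types of the same experiments were 7.89, 5.84 and 8.89. These 3 strains are the ones whose genotypes list a KanMX cassette, and the sequence the probe set reads is not given in the sources used here. Probe set 1771649_at had a mean of 1112 ± 87.3 in the overexpression against 583 ± 72.7 in its wild type (limma adjusted p = 0.0444). Of 571 unnamed probe sets above the filter, 1, 1 and 4 were called in the set1 deletion, the jhd2 deletion and the overexpression.

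With JHD2 overexpression the genome-wide changes followed a pattern seen between wild-type arrays, and the zinc regulon had a median of -0.61 with 3 of its 11 genes called lower. Across genes, which are not independent replicates, the overexpression changes correlated at r = 0.567 with a difference between wild-type arrays of the JHD2 deletion experiment. That difference is replicate 3 against replicates 1 and 2, and the set1 deletion changes correlated with it at 0.0135. These wild-type arrays differ in their 3'/5' ratio and not in strain. They also differ in the signal of a 25S rRNA control probe set (116 and 150 against 4683), which was 263 and 5573 on the 2 overexpression arrays. RNA or labelling quality is thus a candidate cause of the genome-wide shift, and other differences of replicate 3 are not separated from it. For the zinc regulon the covariate does not decide about RNA or labelling quality. The list's median was -0.859 with the ratio as a covariate (camera adjusted p = 4.5e-14 at the preset correlation, while without the covariate the list was not called at an estimated one, adjusted p = 0.397). But the ratios follow the strain here, at 1.44 and 1.43 on the overexpression arrays against 0.88 and 0.66 in their wild type. The covariate's slope therefore rests mostly on the replicate 3 arrays of the JHD2 deletion experiment. The list did not follow the replicate 3 difference of those wild-type arrays (median 0.037), which covers that experiment only. For the gain of JHD2 the tests do not decide, since the list's median in the jhd2 deletion was -0.0897, near 0 and not opposite to the overexpression. The wild type of the overexpression experiment was itself above that of the JHD2 deletion experiment (median 1.12, with 8 of 11 genes called), and against all 7 wild-type arrays as 1 group the list was at 0.0175 (adjusted p = 0.653), so a difference between the wild types or cultures stays open as well.

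Ribosomal protein and glycolysis genes were higher in the jhd2 deletion on the deposited scale. Scaling of bright probe sets is a candidate explanation, and 360 other bright genes moved the same way in each pair, by 0.14, 0.22 and -0.11. Their median over all arrays was smaller, at 0.087 against 0.247 for ribosomal protein and 0.234 for glycolysis genes. Across all tested genes the change correlated with mean signal at a Spearman rho of 0.116. Quantile normalization took the ribosomal protein median from 0.247 to 0.0215, still called by camera (adjusted p = 0.000716), while median centring gave 0.318. Quantile normalization makes the bright ends of all arrays alike. It would also shrink a real rise of these genes, so it does not decide whether scaling is the cause. The loss of JHD2 cannot be told apart from scaling, because 2 of the 3 same-numbered pairs had a higher ribosomal protein median and pair 3, with the higher 3'/5' ratios, a lower one.

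ASP3-1 was called lower in both strains that carry the jhd2 deletion cassette. An effect of the level of JHD2 that runs in opposite directions with loss and gain is argued against, since ASP3-1 was at -1.19 ± 0.20 with overexpression and at -1.12 ± 0.17 with deletion. A strain difference at the repeat, shared by both strains, is a candidate explanation: besides ASP3-1, whose -1.12 is the highest of the 3 repeat probe sets and belongs to the pattern itself, YLR156W and YLR157W-E lay between -1.94 and -1.56 in both comparisons, while RNH203, ACS2 and MAS1, beside the repeat, stayed within 0.19 of 0. YLR156W and YLR157W-E did not pass with overexpression (adjusted p = 0.196 and 0.148), with deletion they passed with the replicate block and not without it, and in the set1 deletion, which has no jhd2 cassette, they were at -0.78 ± 0.59 and -0.90 ± 0.50 without passing and ASP3-1 at -0.17 ± 0.20. Copy number was not analysed here, and the strain difference and the loss of the native JHD2 locus, common to both strains, stay open.

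The 10 splits of the 6 arrays of the JHD2 deletion experiment are too few for a share under 0.05, the smallest possible being 0.1. The real split called 2 genes, 3 of the 10 splits, the real one among them, called at least as many, and the highest of the others called 71. That split exchanges the replicate 3 arrays between the groups and parts all 3 pairs, as the real one and 4 splits in all do, and with that many calls it points to a structure of the samples, whose cause was not tested. With the replicate block the real comparison called 4 genes.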

How the results depend on the processing

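The tests with the 3'/5' ratio as a covariate, with both replicate 3 arrays of the JHD2 deletion experiment left out, and with a crossed block were chosen after seeing the data, and the other alternatives before. Of 1119 comparisons of 40 named gene results with an alternative, 820 kept direction and call, 296 kept direction and lost the call, and 3 reversed. Of 784 for 28 called list results, 673 kept both, 102 lost the call and 9 reversed, the direction being that of camera, which a median near 0 need not share. The calls of JHD2 in the deletion and in the overexpression, of CHA1 in the overexpression and of 3 lists were kept in all of these comparisons, which for lists leave out the estimated correlation, under which every list lost its call, and fry. The main counts were 14 genes for the set1 deletion, 2 for the jhd2 deletion and 28 for the JHD2 overexpression. They were 4, 14 and 5 for the differences between set1 and jhd2 deletion, set1 deletion and overexpression, and jhd2 deletion and overexpression. Between wild types they were 21 (JHD2 deletion and SET1 experiments), 439 (overexpression and SET1) and 880 (overexpression and JHD2 deletion). Unless a cause is given below, the cause was not tested.

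Quantile normalization gave 1 gene for the jhd2 deletion, 121 for the overexpression, 27 for the difference of set1 deletion and overexpression and 1 shared by jhd2 deletion and overexpression. It called 8 lists in the jhd2 deletion in place of 13, and reversed the medians of histone genes (-0.0339) and meiosis genes (-0.11) there. Median centring gave 1 gene for the jhd2 deletion, 13 for the overexpression and 1 shared by both. Neither scaling reversed a called gene that is named. The stricter filter gave 22 genes for the set1 deletion, and the mean of probe sets 26. A pseudocount of 32 gave 28 genes for the set1 deletion, 8 for the difference of jhd2 deletion and overexpression, and 1 shared by set1 deletion and overexpression.

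Without the intensity trend the counts were 27 for the set1 deletion, 1 for the jhd2 deletion, 11 for the overexpression, 26 and 8 for the differences of the overexpression from set1 and jhd2 deletion, and 1 shared by jhd2 deletion and overexpression. Array weights gave 231 genes for the jhd2 deletion (199 higher), 1055 for the overexpression (460 higher), 25 and 870 for those differences, 1773 between the wild types of overexpression and JHD2 deletion, and 1 and 19 shared by the overexpression with set1 and jhd2 deletion. Only the arrays compared gave 0 genes for the set1 deletion (370 at an unadjusted p under 0.05 in limma), 1 for the jhd2 deletion, 955 for the overexpression, 62 for the difference of set1 deletion and overexpression, 764 between the wild types of overexpression and SET1, and 1 shared by jhd2 deletion and overexpression.

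With all 7 wild-type arrays as 1 group the overexpression had 223 genes, and the differences 27, 729 and 641. The correlation of set1 deletion with jhd2 deletion was -0.0524 and with overexpression -0.217, 2 genes were shared with the overexpression, and 14 and 17 lists were called in set1 deletion and overexpression. This setting reversed MF(ALPHA)1 (-5.25) and MF(ALPHA)2 (-4.60) in the set1 deletion, OPT2 in the overexpression (0.16), the phosphate and iron medians in the set1 deletion (0.0372 and 0.0377) and, in the jhd2 deletion, the a-specific (-1.62), meiosis (-0.12) and thiamine (-0.14) medians. By its construction it joins wild types whose mating-type genes differ, which changes the pheromone and a-specific values. In the overexpression it ended the calls of the zinc list (median 0.0175, adjusted p = 0.653), the chaperone list (0.0185, 0.898), ZPS1 (-0.10, 0.964), INO1 (-0.72, 0.579) and ADH4 (-0.79, 0.149).

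The replicate block of 7 numbers gave 110 genes for the set1 deletion (55 higher and 55 lower), 4 for the jhd2 deletion and 1105 for the overexpression (482 and 623), with 10, 585 and 544 for the differences and 30 and 4 genes shared by the overexpression with set1 and jhd2 deletion. Same-numbered deviations correlated at 0.73 in the SET1 experiment, across genes, and at -0.14 in the overexpression experiment, where the numbers do not pair the arrays. Crossing that experiment's pairing gave 157, 5 and 1175 genes, with 20, 646 and 618 for the differences, 47 and 5 shared, and 3 lists in the overexpression. In the jhd2 deletion the block called 12 lists, 10 of them among the 13 without it, and added YLR156W and YLR157W-E to the called genes. It kept 8 of 9 lists in the set1 deletion and 4 of 6 in the overexpression, and kept every gene called without it in the 3 comparisons. Genes that did not pass without it were compared by count only.

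With the 3'/5' ratio as a covariate the set1 deletion had 42 genes, the differences of the overexpression from set1 and jhd2 deletion 23 and 13, and the wild types 65, 897 and 1366. Without both replicate 3 arrays the counts were 38, 169 (162 higher) and 698 (246 higher) for the 3 comparisons, 252 and 352 for those differences, 137 and 1155 between the SET1 wild type and the other wild types, and 7 and 9 shared by the overexpression with set1 and jhd2 deletion. An adjusted p under 0.1 gave 30 genes for the set1 deletion, 109 for the overexpression, 11 and 26 for the differences of the set1 deletion from jhd2 deletion and overexpression, 37, 856 and 1372 between wild types, and 2 shared by set1 deletion and overexpression. An absolute log2 change of 1 or more left 186 and 331 genes between the overexpression wild type and the other wild types. With the estimated correlation camera called 0 lists in each comparison, where the preset correlation called 9, 13 and 6. Directional fry called 2, 1 and 1 lists, and mixed fry 12 in the set1 deletion, 1 in the jhd2 deletion and 14 in the overexpression.

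Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 3 to 24 genes for the set1 deletion, 1 to 24 for the jhd2 deletion and 5 to 157 for the overexpression. The differences had 4 to 8, 6 to 18 and 4 to 65 genes, and the wild types 17 to 224, 124 to 658 and 257 to 1061. The correlations ranged from 0.05 to 0.17 (set1 and jhd2 deletion), -0.06 to 0.11 (set1 deletion and overexpression) and -0.38 to 0.31 (jhd2 deletion and overexpression), and the shared genes from 0 to 0, 0 to 2 and 1 to 3. Lists called ranged from 6 to 12, 8 to 14 and 4 to 10. In the set1 deletion the chaperone median ranged from -0.0175 (without wild-type replicate 1) to 0.27 and the ribosome biogenesis median from -0.0120 (without wild-type replicate 2) to 0.39. Same-numbered arrays of the SET1 experiment vary together, so leaving out 1 also breaks a pair, and these ranges do not separate the 2. For the 3 main comparisons the highest counts came without jhd2 deletion replicate 3 (set1 and jhd2 deletion) or without wild-type replicate 3 of that experiment (overexpression). The lowest came without set1 deletion replicate 1 (set1 deletion) and overexpression replicate 2 or wild-type replicate 1 of that experiment (overexpression). Signal over background limits little, since 98.0% or more of the tested genes were above it on each array, except for genes silent in a group, whose folds are lower bounds.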

Other observations

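The tests of lists between wild types and of phospholipid genes in this part were chosen after the results were seen. The list of NAD synthesis genes was fixed earlier, and the genes named from it follow its values.

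In the set1 deletion the genes of the kynurenine pathway, which makes NAD from tryptophan, moved in both directions. BNA2, for the dioxygenase of the first step, was at 1.52 ± 0.29 (log2, SE, n = 2 against 2, limma adjusted p = 0.0505), BNA4, for the monooxygenase, at 0.72 ± 0.16 and TNA1, for the nicotinic acid permease, at 0.54 ± 0.16. BNA7, for the formamidase that acts between these enzymes, BNA5, for kynureninase, and BNA6, for quinolinate phosphoribosyltransferase, were at -0.70 ± 0.17, -0.63 ± 0.16 and -0.59 ± 0.17, and NPT1, for the salvage enzyme of nicotinic acid, at -0.28 ± 0.10. None passed over all genes, and these 7 of 11 passed adjusted over the list alone, each in the same direction after quantile normalization and median centring. The list as a whole did not pass camera (adjusted p = 0.312).

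The wild type of the overexpression experiment differed from that of the JHD2 deletion experiment in nutrient pathways. LEU2 signals differed between them as well (means of 7085 and 20.7), and the growth medium is not given. Strain, medium and other differences between the experiments are therefore not separated here. Of 33 sulfur and methionine genes 21 were higher (median 0.77, camera adjusted p = 0.0278 with an estimated correlation), among them the sulfite reductase gene MET10 (2.45 ± 0.13). All 8 arginine biosynthesis genes were higher (median 1.83), with the ornithine carbamoyltransferase gene ARG3 at 4.38 ± 0.40. Of 19 genes of the phosphate regulon 12 were lower (median -0.97), with the high-affinity phosphate transporter gene PHO84 at -3.19 ± 0.34. The zinc transporter gene ZRT1 and the vitamin B6 gene SNZ1 were higher by 3.30 ± 0.37 and 3.91 ± 0.27, and the copper-regulated reductase gene FRE7 was at -4.14 ± 0.35. Of 68 stress-induced genes 28 were higher (median 1.14), and 17 of 106 ribosome biogenesis genes were lower (median -0.33). The estimated correlation left the arginine, phosphate, stress and ribosome lists uncalled (adjusted p = 0.145, 0.182, 0.508 and 0.442).

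A hypothesis was that JHD2 overexpression lowers phospholipid synthesis genes that respond to inositol and choline as a group, beyond INO1, CHO1 and OPI3, which were called. Of 18 such genes 16 were negative, and 10 were lower adjusted over the list alone. Among the 15 not called, 13 were negative, with a median of -0.52, for example the choline kinase gene CKI1 (-1.03 ± 0.26), the choline transporter gene HNM1 (-0.72 ± 0.18) and the fatty acid synthase gene FAS2 (-0.52 ± 0.11). Camera gave p = 6.5e-06 for these 15 genes at the preset correlation, and p = 0.0131 with an estimated correlation, both unadjusted. With the 3'/5' ratio as a covariate their median was -0.36 (camera p = 5.0e-09, unadjusted, at the preset correlation). The ratio follows the strain in this experiment, so the covariate does not decide about RNA or labelling quality for these genes. The medians were -0.57 after quantile normalization and -0.51 after median centring. These values are in line with a shared lower level of the group, which may follow from the strain, from inositol or choline in the medium, or from a wild type in which the group stood 0.59 above that of the JHD2 deletion experiment, and the tests do not separate these. The group's median was -0.05 in the jhd2 deletion and 0.09 in the set1 deletion.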
